A study of Mus musculus with 4 samples.

How the data were processed

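The data were ATAC-seq peak lists of mouse SMARTA CD4 T cells from tumor-draining lymph nodes, with 2 WT and 2 KO libraries named WT-1, WT-2, KO-1 and KO-2 after genotype and replicate number in the labels. Per the labels' protocols, sorted cells were frozen in 10% DMSO in serum, thawed, lysed and transposed at 42 °C for 45 min, and the DNA was amplified for 5 cycles plus further cycles set by real-time PCR. Sequencing was paired end with 50 bp reads.

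Per the submitters' processing notes, BWA, SAMtools, Picard, MACS2 and deepTools were used with the builds GRCm38 and mm10, which are names of the same assembly. Their versions, settings and order are not given in the sources used here, nor is how reads were shifted for the transposase or which filters were applied. Each deposited list had 10 columns and no header, in the layout of narrow peaks, and belonged to 1 library, so replicates could be compared. The deposited fold enrichment is a ratio of the peak to the caller's background in the same library. The deposited −log10 p and −log10 q values rank a peak against that background, and every deposited −log10 q was above 2. The deposited score was 10 times the −log10 p for at least 99.97% of peaks in each library and was not used. These values per peak are the authors' own and served here only to describe, rank or filter peaks within a list. Peaks lay on the autosomes and X. Peak numbers followed the order of p, and 1603, 1681, 1758 and 1900 numbers were missing in KO-1, KO-2, WT-1 and WT-2. Of these, 231, 251, 237 and 256 fell in the strongest 10% of a list, so peaks of every strength had been removed from the lists. Where the removed peaks lay is not known, and they may have lain outside the autosomes and X. An absent peak can therefore be a removed peak, but no single case of this is shown.

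Read numbers are not given, so depth is unknown and no counting interval could be set. The most frequent pairs of fold and p in each list matched a Poisson test with a pseudocount of 1, with a largest mismatch of 1.64e-05 in −log10 p. They gave a background of 5.11 tags in KO-1, 3.29 in KO-2, 5.54 in WT-1 and 6.08 in WT-2, which follows depth if the caller used the same settings.

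Overlapping peaks of the 4 lists (at least 1 bp) were merged into regions. A WT-only region had a peak in both WT and neither KO library, and a KO-only region the reverse. A region was assigned to the protein-coding gene with the nearest interval within 100 kb of its midpoint (84.99% of regions), from a table of RefSeq genes on GRCm38.p6 without strand, exons or sequence. The plan had named transcription start sites. The nearest gene interval, and 1 kb from either gene end, took their place, and "upstream" became either side. Exon, intron and UTR shares and the planned search for 23 sequence motifs were not run because no genome sequence was used here. All positions are 1-based.

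Regions per genotype and class were counted without a test across libraries. Location was compared by a two-sided Fisher exact test with regions as units. Each gene list was compared, by WT-only minus KO-only regions as a percent of its regions, with 10000 random lists drawn from genes with a region and matched on regions per gene in 8 classes. This permutation test was two-sided and adjusted by Benjamini-Hochberg over 18 lists, with an adjusted p of 0.05 as threshold. The 3 lists written later were adjusted over those 3, and the lists left after B cell and myeloid genes were taken out were adjusted among themselves. The comparisons, gene lists and alternatives were fixed before the data were examined. The alternatives were stricter peaks (−log10 q of at least 5 or 10), an asymmetric threshold, lists cut to equal length, other overlap rules, autosomes alone, narrower gene assignment, each replicate left out and a replicate block.

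The genes named by rule were Tox, Pdcd1, Lag3, Entpd1 and Ptprc; members of the lists with a genotype-specific region, up to 4 examples a list by the largest absolute difference; and the 10 genes with most WT-only and no KO-only regions, and the reverse, with ties going to the larger share of the gene's regions. An item that this rule selects is not reported here. The 5 WT-only and 5 KO-only regions with the highest minimum percentile of −log10 q were named too. Tbx21, Lat and the genes in the closing part of the text that fall outside this rule were chosen after their values were seen. Mx1 of the interferon list is not protein-coding in the table and stayed out.

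The list test was tested on simulated data made from the 16487 real genes, with the WT-only and KO-only marks shuffled over all regions. Shuffling removes any gathering of marks at single genes, and p was not adjusted. The recovery below can therefore be higher than that of the adjusted calls on the real marks. Among 100 random lists of 20 genes, 6 were called at a p of 0.05 with nothing added, 76 when 10% of their regions were turned to WT-only, and 100 when 20% were. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.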

Results

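Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in SMARTA CD4 T cells of the mouse. SMARTA cells carry a transgenic T cell receptor for the GP61 peptide, and B16-GP61 is a melanoma line made to express it. Naive donor cells with TOX (WT) or without it (KO) had been transferred into tumor-bearing mice treated with cytoxan, an alkylating drug that depletes lymphocytes, and were sorted from the tumor-draining lymph node on day 11. TOX is an HMG-box DNA-binding protein known from T cell development and exhaustion, and the series title links it to the Th1 effector function of CD4 T cells. The WT cells were sorted as Ly5.1+ Ly5.2+ with high PD1, LAG3 and CD39, and the KO cells as Ly5.1+ Ly5.2- with low levels of these 3 proteins. Genotype, sort gate and congenic marker therefore changed together, and a difference between WT and KO libraries belongs to all of them. There were 2 libraries of each genotype, each with its own list of peaks, and nothing in the labels says whether they came from separate animals. A test with 2 libraries against 2 cannot give an exact two-sided permutation p below 0.33. The p-values below take regions or genes as units, so they describe these 4 libraries.

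At Tox itself (GRCm38, chromosome 4, 6686353 to 6991557) both WT libraries had a peak across the upper end of the gene, where transcription of Tox starts, and neither KO library did. This region, 6990165 to 6991572, had a deposited fold enrichment of 6.57 in WT-1 and 7.12 in WT-2. It was the only WT-only region among the 57 regions within 100 kb of Tox, of which 21 had a peak in every library. Another 7 of these regions had a peak in both KO libraries and in neither WT library, and the strongest of them lay at 6663202 to 6664200, outside the gene. The labels do not give the deleted part of Tox, so the missing peak separates the libraries as labelled but is not by itself a check of the deletion.

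**Figure D1:**
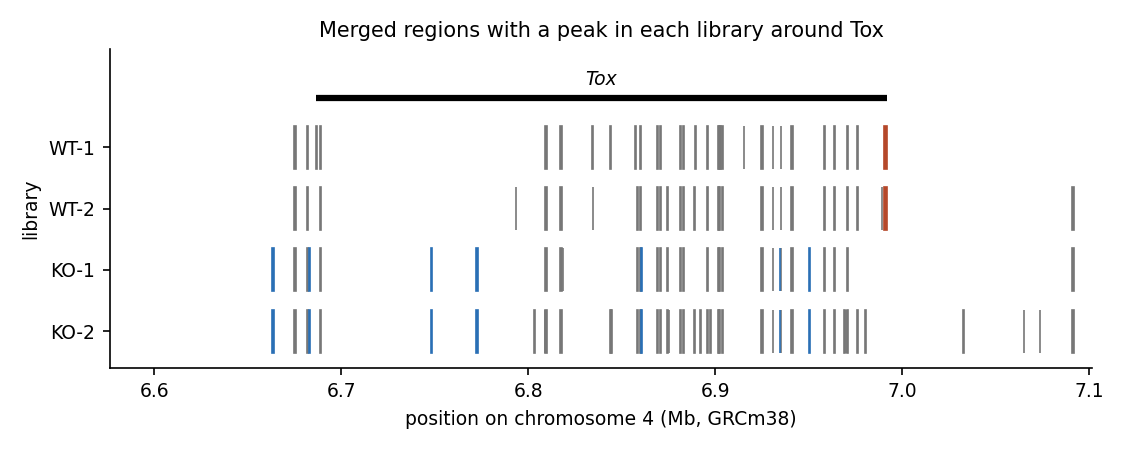
Merged regions around Tox by position on chromosome 4 (Mb, GRCm38), with a row for each library and a mark wherever that library had a peak. Red marks the WT-only region at the upper gene end, blue the 7 KO-only regions and grey the others; the black bar is the gene, and narrow regions are drawn with a minimum line width.

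The genes whose proteins set the sort gate showed few genotype-specific regions. Pdcd1, which encodes PD1, had 1 KO-only region of 14, at chromosome 1, 94078759 to 94079024, outside the gene interval. Lag3 had 1 KO-only region of 8, inside the gene at chromosome 6, 124907846 to 124908118. Entpd1, which encodes CD39, had 1 WT-only region of 14, inside the gene at chromosome 19, 40660555 to 40661467. Ptprc, the gene of the Ly5 congenic marker, had 3 WT-only regions and 1 KO-only region of 37. No test was run on single genes.

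By covered bases, the libraries of a genotype shared more of their open chromatin than libraries of different genotypes, by a narrow margin for the KO pair. The WT lists held 56852 and 61489 peaks, 59170.5 ± 3279 (SD, n = 2), and the KO lists 43078 and 61773, 52425.5 ± 13219 (SD, n = 2). The difference of the means was smaller than the SD of the KO libraries. KO-1 had the shortest list, and its peaks covered 20.9 Mb, against 27.6 Mb in KO-2, 26.8 Mb in WT-1 and 29.6 Mb in WT-2. The Jaccard index of covered bases was 0.633 between the WT libraries and 0.537 between the KO libraries. The 4 pairs of a WT with a KO library lay between 0.494 and 0.523. By the share of overlapping peaks, KO-2 did not stand closest to KO-1. Of the KO-2 peaks, 53.5% overlapped a peak of KO-1, 60.4% of WT-1 and 63.2% of WT-2. Of the KO-1 peaks, 77.9% overlapped a peak of KO-2, 72.6% of WT-1 and 75.1% of WT-2. This share also depends on the length of the other list, and KO-1 had the shortest. Read numbers are not given in the sources used here, so the depth of each library is unknown.

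More regions had peaks in the WT libraries alone than in the KO libraries alone, but the order depended on the libraries and on the strength of the peaks counted. Of 97394 merged regions, 26867 (27.6%) had a peak in every library. Another 8567 (8.80%) were WT-only, with a peak in both WT libraries and in neither KO library, and 1737 (1.78%) were KO-only, a ratio of 4.93. The genotype split left 10304 regions private to one pair of libraries, against 2548 and 1930 for the other 2 ways of pairing the libraries. Those ways cross the genotypes and were uneven as well. KO-1 with WT-1 had 283 private regions against 2265 for KO-2 with WT-2. KO-1 with WT-2 had 476 against 1454 for KO-2 with WT-1. In each split the smaller side held KO-1, so the ratio of 4.93 does not by itself tie the excess to genotype. Leaving out a library loosens the rules for both classes, since neither its peak nor its absence is then required, so neither count can fall. With KO-2 as the sole KO library there were 9332 WT-only and 20033 KO-only regions, and with KO-1 as the sole one 14109 and 9215. With WT-2 or WT-1 as the sole WT library there were 21238 and 2504, or 17293 and 3237. The 20000 strongest peaks of each library gave 2360 WT-only and 1785 KO-only regions. With KO-2 set against a WT library alone, strong peaks (−log10 q of at least 10) absent from the other list numbered 3171 in WT-1 against 1527 in KO-2, and 3904 in WT-2 against 1180. For peaks of any strength these counts were 18341 against 23798 and 22479 against 22254.

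**Figure D2:**
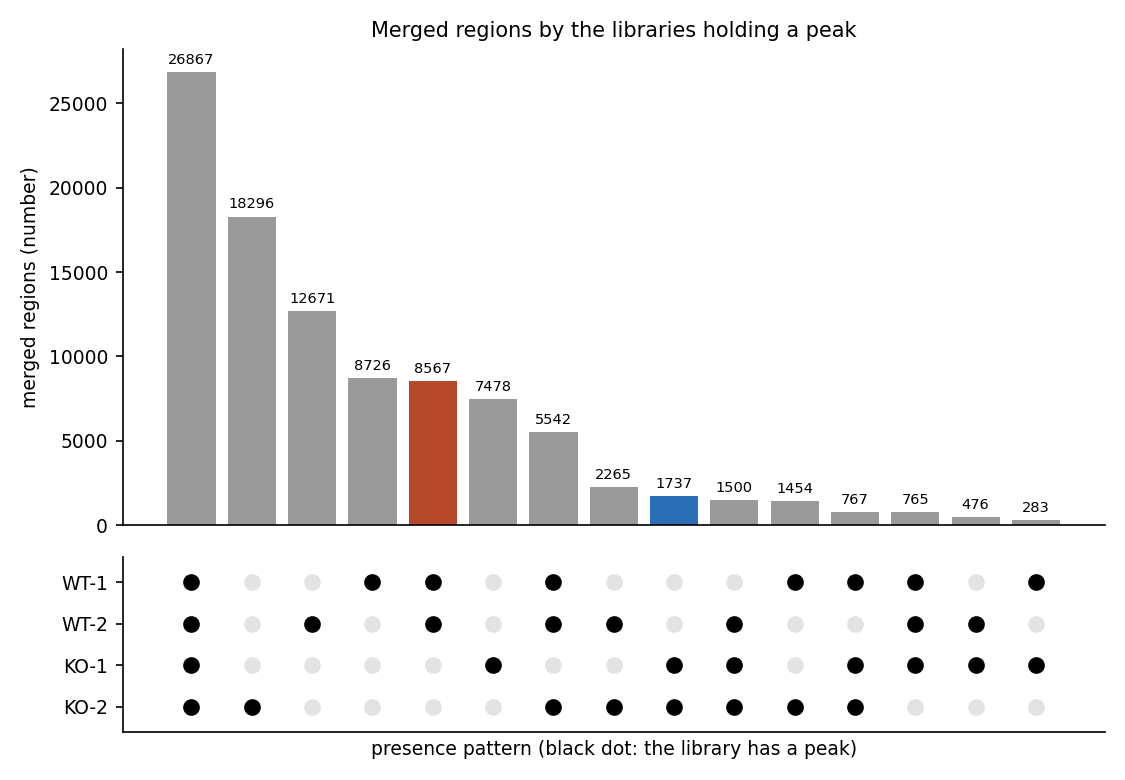
Number of merged regions (vertical axis) for each combination of libraries with a peak, marked by black dots under the bars. The 8567 WT-only regions (red) outnumber the 1737 KO-only regions (blue), and the 18296 regions of KO-2 alone are the most numerous private set.

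Genotype-specific regions of either kind lay mostly away from gene ends. Within 1 kb of an end of a protein-coding gene lay 7.54% of the WT-only and 6.51% of the KO-only regions, against 36.01% of the regions shared by the 4 libraries. The shared regions were also wider and had stronger peaks, and this contrast was not matched for either. Gene bodies held 50.8% of the WT-only and 54.1% of the KO-only regions, and 41.7% and 39.4% lay outside genes. The share near gene ends did not differ detectably between WT-only and KO-only regions (odds ratio 1.17, two-sided Fisher exact p = 0.144). This call changed with the setting. Among peaks with a deposited −log10 q of at least 10 the odds ratio was 2.18 (Fisher exact p = 5.63e-06), and with peaks joined by their summits it was 0.599 (Fisher exact p = 8.46e-14).

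For the Th1 program named in the series title, WT-only regions stood at several effector genes, yet the list as a whole did not differ from random genes. Fasl, the ligand of the death receptor Fas, had 6 WT-only regions of 24 and no KO-only region. Bhlhe40, a transcription factor needed for interferon production by T cells, had 6 of 17 and no KO-only region. Ifng, the gene of interferon gamma, and Runx3, which cooperates with T-bet, each had 3 WT-only regions, of 26 and 30, and no KO-only region. The shares at Ifng and Runx3 were close to the 8.80% of all regions that were WT-only, and those at Fasl and Bhlhe40 were higher. The 3 at Ifng lay outside the gene on chromosome 10, at 118406855 to 118407351, 118480814 to 118481480 and 118501448 to 118502042. Regions with a peak at Ifng numbered 20 in WT-1, 20 in WT-2, 19 in KO-2 and 11 in KO-1. Tbx21, which encodes T-bet, had neither kind. The Th1 list held 33 WT-only and 4 KO-only regions of 240, a difference of 12.1% of its regions, against 8.72% on average in random lists matched on regions per gene (adjusted permutation p = 0.446). Cytotoxic genes gave 21 and 3 of 132 regions, a difference of 13.6% (adjusted permutation p = 0.394), with 4 WT-only regions at Slamf7 and 3 at Klrg1, receptors of effector cells. The gap of the cytotoxic list to random lists, 5.196 percentage points, was 16.5 without KO-2, where it passed (adjusted permutation p = 0.0366), and −17.1 with the 20000 strongest peaks of each library, where it did not (adjusted permutation p = 0.116). The comparisons of these lists with random lists were two-sided, used 10000 of them and were adjusted by Benjamini-Hochberg over the 18 lists.

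Genes of inhibitory receptors and T cell exhaustion had as many KO-only as WT-only regions, 7 of the KO-only ones at Tox. This list had 21 WT-only and 21 KO-only regions of 329, a difference of 0%, where matched random lists averaged 8.63% (adjusted permutation p = 0.0162). Of its 22 genes, 9 had more WT-only and 8 more KO-only regions. Tox had 1 WT-only and 7 KO-only regions, Cd200 had 0 and 2, Rbpj had 3 and 0, and Prdm1, which encodes the repressor Blimp-1, had 4 and 2. Without Tox the list had 20 and 14 of 272 regions and no longer passed (adjusted permutation p = 0.0624), while its gap to random lists was −6.92 percentage points against −8.63 with Tox. The call held in 8 of 17 alternative settings, with a difference below that of random lists in each, and ended without KO-1 (gap −6.57, adjusted permutation p = 0.484) or KO-2 (gap −10.5, adjusted permutation p = 0.0603).

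Pan T cell genes and regulatory T cell genes lay below random lists as well. Gaps to random lists as large stood at housekeeping genes (−9.96 percentage points, 43 regions) and melanocyte genes (−10.9, 35 regions). Those lists, with fewer regions, did not pass (adjusted permutation p = 0.225 for each). A gap of the size seen here and for the exhaustion list was therefore not found at T cell genes alone. The pan T cell list, of genes that T cells use in general, had 10 WT-only and 13 KO-only regions of 191, a difference of −1.57% against 8.17% in random lists (adjusted permutation p = 0.0369). Thy1 had 3 KO-only regions and no WT-only region, Cd28 and Lat each had 2 KO-only regions and no WT-only region, and Cd2 had 4 WT-only regions and no KO-only region. The regulatory T cell list had 8 and 10 of 178, a difference of −1.12% (adjusted permutation p = 0.045), with 3 KO-only regions at Il1rl1, the IL-33 receptor gene, and 4 KO-only against 2 WT-only at Nrp1. The pan T cell call held in 10 of 16 alternative settings and the regulatory T cell call in 5. Both ended without KO-1 or KO-2, where the pan T cell gap to random lists went from −9.74 to −6.16 or −8.48 percentage points (adjusted permutation p = 0.661 and 0.366) and the regulatory gap from −8.99 to −5.38 or −4.86 (adjusted permutation p = 0.699 and 0.616). Follicular helper genes had 19 and 13 of 276 regions, a difference of 2.17%, which did not pass (adjusted permutation p = 0.0624) but did, below random lists, in 6 of 16 alternative settings. In the same WT libraries B cell and myeloid genes lay above random lists, at 47.2% and 30.9%, and with those genes left out of the random lists the regulatory T cell gap was −8.84 percentage points (adjusted permutation p = 0.0773) against −8.99 with them.

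Of the other T cell lists, none passed. Naive and memory genes had 60 WT-only and 18 KO-only regions of 535 (adjusted permutation p = 0.931), with 15 and 1 at Foxp1, 11 and 5 at Bach2 and 6 and 0 at Foxo1, all 3 transcription factors of resting lymphocytes. Activation genes had 39 and 9 of 376 (adjusted permutation p = 0.948), with 7 and 1 at the ubiquitin ligase gene Cblb and 6 and 0 at Irf8. The Th17 list had 16 and 7 of 141 (adjusted permutation p = 0.836), and 9 of the 16 WT-only regions stood at Ccr6, a chemokine receptor. Foxp1, Bach2, Irf8 and Ccr6 are also used by B cells, whose genes carried WT-only regions in both WT libraries. The Th2 (6 and 4 of 69), interferon response (8 and 1 of 53), cell cycle (2 and 0 of 51) and housekeeping lists (2 and 3 of 43) had adjusted permutation p-values from 0.225 to 0.746. The housekeeping list passed below random lists in 1 of 16 alternative settings. This was without WT-2, where its gap to random lists went from −9.96 to −24.0 percentage points.

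**Figure D3:**
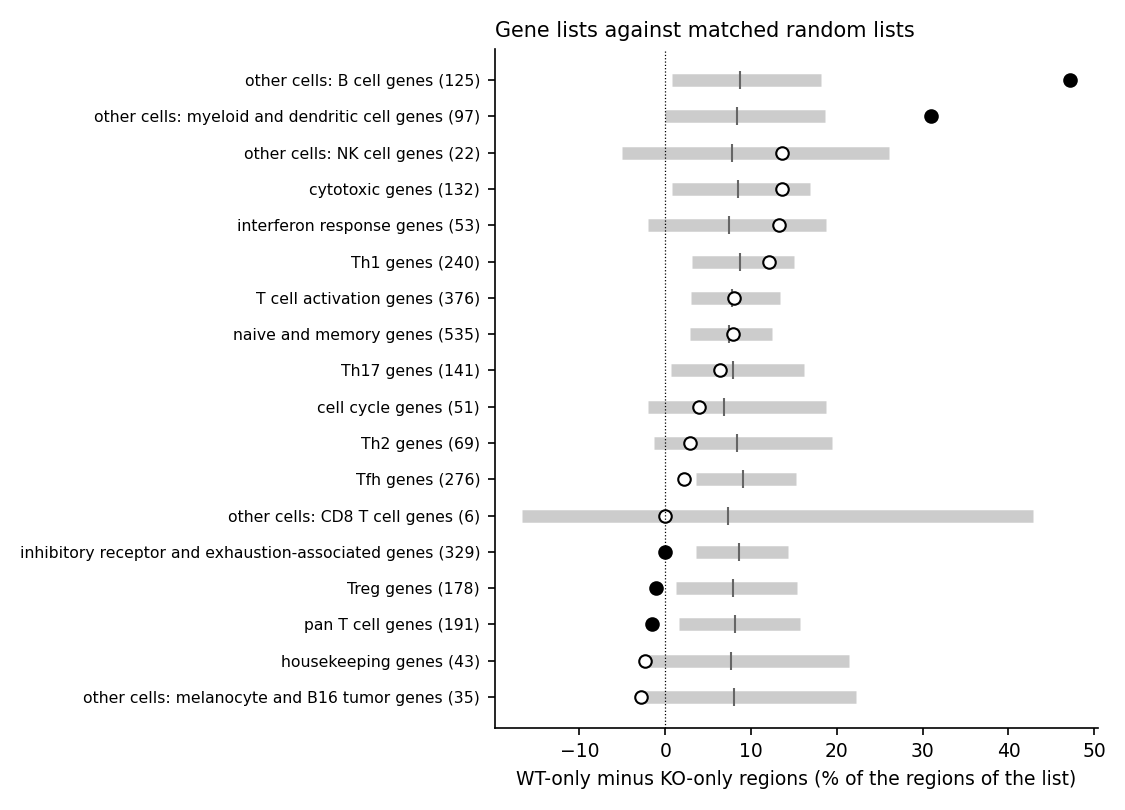
WT-only minus KO-only regions as a percent of the regions of each gene list (horizontal axis; number of regions in parentheses). Grey bars span the central 95% of 10000 matched random lists and ticks their mean; filled points passed an adjusted p of 0.05, with B cell genes at 47.2% and pan T cell genes at −1.57%.

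Among the 18 lists, the largest difference between the genotypes stood at genes of B cells, a cell type that neither gate was meant to hold. The B cell list had 60 WT-only regions and 1 KO-only region of 125, a difference of 47.2% against 8.71% in random lists (adjusted permutation p = 0.0009, from a raw p of 0.0001, the smallest that 10000 lists can give). All 12 of its genes had more WT-only than KO-only regions. Ebf1 and Pax5, transcription factors of the B lineage, had 15 and 0 and 8 and 1 regions of the 2 kinds, and Bank1 and Blk, which act in B cell receptor signalling, had 14 and 0 and 6 and 0. Regions of the list with a peak numbered 98.5 ± 4.95 in WT and 15 ± 5.66 in KO libraries (SD, n = 2 each). For the pan T cell list these numbers were 121.5 ± 0.707 and 126.5 ± 24.7 (SD, n = 2 each). The B cell difference passed in all 15 alternative settings run on it.

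Myeloid and dendritic cell genes also lay above random lists, with 32 WT-only and 2 KO-only regions of 97, a difference of 30.9% (adjusted permutation p = 0.0009). Ly86, which pairs with a Toll-like receptor homolog on B cells and myeloid cells, had 9 and 0, the dendritic cell growth factor receptor gene Flt3 had 5 and 0, Cebpb had 5 and 1, and Adgre1, the macrophage marker F4/80, had 3 and 0. The difference passed in all 15 alternative settings run on it. Lists of other cell types did not pass: natural killer cell genes had 3 and 0 of 22 regions (adjusted permutation p = 0.665), melanocyte and B16 tumor genes 0 and 1 of 35 (p = 0.225, same test), and CD8 T cell genes none of 6 (p = 0.929, same test). The melanocyte list passed below random lists in 3 of 16 alternative settings, among them without KO-1, where its gap went from −10.9 to −32.0 percentage points (adjusted permutation p = 0.0318).

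**Figure D4:**
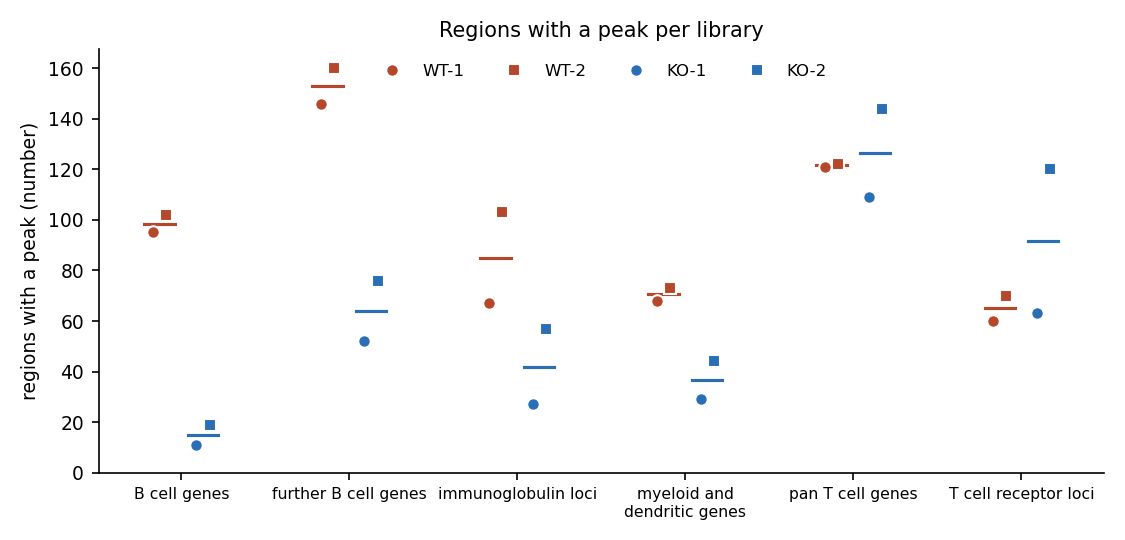
Number of merged regions with a peak (vertical axis) in each library (points; circles replicate 1, squares replicate 2; bars the mean of a genotype, n = 2) for 4 gene lists and 2 sets of loci. B cell genes had 95 and 102 regions in the WT and 11 and 19 in the KO libraries, while pan T cell genes had 121 and 122 against 109 and 144.

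Genes were also ranked by genotype-specific regions without regard to any list. Among the 16487 protein-coding genes with a region, the 10 with most WT-only and no KO-only regions were Ebf1 with 15, Bank1 and Bcl11a with 14, Tns3 and Rftn1 with 11, and Adgrl2, Syk, Hdac9, Mtss1 and Cradd with 10 each. Bcl11a is a transcription factor needed for B cell development, Syk a kinase of the B cell receptor, and Rftn1 a lipid raft protein of B cells. Peaks at Bcl11a numbered 26 ± 5.66 in WT and 3 ± 0 in KO libraries (SD, n = 2 each). Among genes with KO-only and no WT-only regions the counts were smaller, led by Csnka2ip, Acsl6 and Pitpnc1 with 4 KO-only regions each. Pgpep1l, Ankrd50, Tceal3, Tnfrsf19, Dnajc6 and Il1rl1 were among those that followed, with 3 each. Acsl6 encodes an acyl-CoA synthetase and Pitpnc1 a phosphatidylinositol transfer protein.

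The strongest WT-only regions, ranked within each list by the deposited −log10 q, lay between genes. The first was on chromosome 3, 135191705 to 135192486, with Cenpe as the nearest gene at 20077 bp, and had a fold enrichment of 15.5 in WT-1 and 16.3 in WT-2. The next were near Hes1 (chromosome 16, 30038875 to 30039776), near Emcn (chromosome 3, 137288152 to 137289265), on chromosome 5 with no protein-coding gene within 100 kb (68735165 to 68736022), and near Ccr7, which guides lymphocytes into lymph nodes (chromosome 11, 99167946 to 99168629). The strongest KO-only region overlapped Lsm14b (chromosome 2, 180024340 to 180025579), with a fold enrichment of 12.3 in KO-1 and 18.3 in KO-2; as peaks of every strength had been removed from the lists, its absence from the WT lists can be a removed peak. The next overlapped Uvrag (chromosome 7, 99003105 to 99003815), lay 92218 bp from Wwox (chromosome 8, 115444930 to 115445596), lay near Tox as given for that gene, and overlapped Vmn2r102 (chromosome 17, 19691890 to 19692579).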

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

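The immunoglobulin loci, which lie outside the gene lists, were examined after the B cell result was seen. The further lists used here and the tests of its explanations were also chosen then, except the setting with 20000 peaks a library, which was planned. WT-only regions numbered 7 at Igh (chromosome 12, 113256204 to 116009954), 12 at Igk (chromosome 6, 67555636 to 70726754) and 10 at Igl (chromosome 16, 19061752 to 19260844). KO-only regions, the control level, numbered 2 of 77 at Igh, 0 of 59 at Igk and 0 of 19 at Igl. Igh alone was close to the shares over all regions (8.80% WT-only and 1.78% KO-only), and KO-2 had more regions with a peak there (44) than WT-1 (35). At Igl, neither KO library had a peak, while WT-1 had 10 regions with a peak and WT-2 had 19. T cell receptor loci went the other way, with 6 WT-only and 14 KO-only regions against 29 and 2 over the immunoglobulin loci (Fisher exact p = 2.58e-06).

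A candidate explanation is DNA of B cells in the WT libraries, and 20 further B cell genes written down before their values were seen had a difference of 29.9% of their regions (61 WT-only and 2 KO-only of 197, permutation p = 0.0003 adjusted over the 3 later lists), led by Tnfrsf13b with 8 and 0 and the class II regulator gene Ciita with 7 and 0. Longer or stronger WT lists do not account for it, since with the 20000 strongest peaks of each library the first B cell list had 66.7% (22 and 0 of 33 regions). A lower share of T cells that would lift every other cell type alike goes against the 7.55% of regions at neutrophil, erythroid, stromal, epithelial and melanocyte genes that were WT-only (8 of 106, Fisher exact p = 2.79e-12 against the B cell list). By list, this share was 15.8% for neutrophil and erythroid, 9.62% for stromal and epithelial and 0% for melanocyte genes. The myeloid and dendritic list, left out of this set, had 33.0%. A lift of some other cell types together with B cells therefore stays open. Opening of B cell loci in the WT T cells themselves cannot be told apart from B cells by a peak list, although the pan T cell list stood at −1.57%, and genotype and gate stay open together. The CD4 gate would remove free B cells, while the Ly5.2+ WT gate could hold pairs of a T cell and a host B cell if the hosts carried Ly5.2, which the labels do not say and the Ly5.2- KO gate would exclude. In the myeloid and dendritic list, 6 genes also used by B cells, dendritic cells or progenitors had 24 WT-only and 1 KO-only region of 68, and the other 9 genes had 8 and 1 of 29.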

How the results depend on the processing

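The comparisons of 1 WT with 1 KO library, the counts outside B cell genes, the random lists without B cell and myeloid genes and the exhaustion list without Tox were chosen after the data were seen. The causes of the shifts were not tested, except that leaving out a library loosens the rules for both classes and that stricter or shorter lists hold fewer regions. WT-only regions numbered 4695 at a −log10 q of at least 10, 4658 under the asymmetric threshold and 2360 with 20000 peaks a library; KO-only regions numbered 1090, 660 and 436 at 5, at 10 and under the asymmetric threshold. Leaving out each library in turn gave 9332 to 21238 WT-only and 2504 to 20033 KO-only regions. Their log2 ratio, 2.30, became 3.42 under the asymmetric threshold, 1.29 at the length of the shortest list, 0.40 with 20000 peaks, and −1.10 (without KO-1) to 3.08 with a library left out. For strong peaks it was 4.52 for WT-1 against KO-1, 1.05 for WT-1 against KO-2 and 5.44 for WT-2 against KO-1. Outside B cell genes it was 2.28. The odds ratio for gene ends passed at a −log10 q of 5 (1.34) and 10 (2.18) and with 20000 peaks (1.84), turned with joined summits (0.599), was 0.995 at 2 kb without passing, and ran from 1.00 to 1.98 with a library left out, passing without KO-1 (1.98) and without KO-2 (1.43). The number of lists that passed, 5, became 2 under the asymmetric threshold, 2 with genes within 10 kb, 2 within 20 kb and 2 of those left in random lists without B cell and myeloid genes, and ran from 3 to 7 with a library left out. The B cell and myeloid lists passed in each setting run on them. The replicate block took WT minus KO presence per region, averaged over the same-numbered libraries. This average is the same for any pairing, so it cannot test pairing, and it also counts regions outside the WT-only and KO-only classes. With it 4 lists passed. The exhaustion, regulatory and pan T cell lists no longer passed (adjusted permutation p = 0.099, 0.263 and 0.203). Their gaps to random lists were −11.0, −10.1 and −11.9 percentage points, in another measure than the main −8.63, −8.99 and −9.74. Follicular helper and melanocyte genes passed below random lists (adjusted permutation p = 0.0216 and 0.045). Over regions, WT-1 minus WT-2 presence correlated at −0.0153 with KO-1 minus KO-2 presence. The labels do not say that a number marks shared mice, so the numbers were not taken to pair the libraries, and whether they do stays open. Other values for the main results stayed within a tolerance set for each kind of value in 43 cases. For odds ratios the tolerance was the side of the threshold alone, whatever their size. One case was the WT minus KO difference in mean peaks per library (6745, and 9041 at a −log10 q of 5). Its tolerance, the SD within genotypes, was wider than the difference itself, so this case says little. Another was the mean Jaccard index within minus between genotypes (0.0743, 0.0868 at equal length, 0.0823 under the stricter overlap rule). The lowest Jaccard index within a genotype exceeded the highest between genotypes by 0.0143. Under the stricter overlap rule, counted over regions rather than bases, it did so by 0.0059. For single lists, 250 values kept their side of the threshold, of which 33, none past it, moved across the mean of random lists; 26 fell short of the threshold and 11 newly passed. The alternatives for sequence motifs were not run. Depth is unknown and limits what an absent peak can show.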

Other observations

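The tests here were chosen after the results were seen. KO-only regions gathered around Tox on chromosome 4. The 4 Mb window from 4 to 8 Mb held 22 KO-only and 6 WT-only regions of 151, and the next highest of 664 windows, on chromosome 11 from 52 to 56 Mb, held 13 KO-only regions. Within 2 Mb of Tox, 28 of 210 regions were KO-only (13.3%), against 1.78% of all regions. T cell receptor alpha and delta loci held 10 KO-only and 3 WT-only regions of 93, and the beta locus 3 and 3 of 45.

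Among the 3 lists written later, over which these p-values were adjusted, neutrophil and erythroid genes had 3 WT-only and 0 KO-only regions of 19 (adjusted permutation p = 0.278), and stromal and epithelial genes 5 and 1 of 52 (adjusted permutation p = 0.912). Among the 20 further B cell genes, the class II genes H2-Ab1, H2-Aa and Cd74 had 3, 2 and 3 WT-only regions and no KO-only region. Cd40, which receives help from CD4 T cells, had 3 and 0, and Btk and Cd37 had none of either kind.

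Independent scatter of KO-only regions does not account for the cluster at Tox, since 1000 random choices of as many regions gave at most 20 in a window (permutation p = 0.001, the smallest they can give). The choices drew neighbouring regions independently, so they do not cover nearby regions that change together. Of the 22 KO-only regions in the window, 7 lay within 100 kb of Tox. Another candidate explanation is that T cell regions are diluted in the WT libraries. The share of 13.3% within 2 Mb was above the 6.81% at pan T cell genes (odds ratio 2.11, Fisher exact p = 0.0329). The 15.7% within 1 Mb was above it too (Fisher exact p = 0.0156), and within 5 Mb the share was 7.71% (Fisher exact p = 0.738). These flanks are nested, with 28 KO-only regions of 210 within 2 Mb and 29 of 376 within 5 Mb. The 5 Mb value thus mostly adds regions beyond the cluster and does not speak for dilution. Dilution stays open, because the flanks were chosen after the cluster was seen and the tests take neighbouring regions as independent. A stretch of chromosome 4 from another mouse strain, carried along with the Tox allele, may also bring such a cluster; no sequence was used here, and it was not tested.

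The excess of WT-only over KO-only regions could come from lower depth in the KO libraries, whose backgrounds of 5.11 and 3.29 tags lay below the 5.54 and 6.08 of the WT libraries, yet KO-2, with the lowest background, missed 22.4% of the 41741 regions of both WT libraries and KO-1 missed 33.8%. Depth stays open, since read numbers are unknown. Weak enrichment in KO-1 alone also stays open: strong WT peaks without a KO-2 peak were 2.08 times as many as the reverse for WT-1 and 3.31 times for WT-2, but for peaks of any strength the counts were 18341 against 23798 for WT-1 and 22479 against 22254 for WT-2. B cells cannot be told apart as a cause, because the genes of both B cell lists held 1.41% of the WT-only regions and other loci open in B cells were not listed. The genotype and the gate remain untested as causes.

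The strongest KO-only region, at Lsm14b, had a −log10 q of 154.7 in KO-1 and 315.7 in KO-2 and no peak in either WT list. Peaks of every strength are missing from the deposited lists, so this absence can also be a removed peak, although where the missing peaks lay is not known.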
